A study of Mus musculus with 60 samples.

How the data were processed

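The series measured RNA of sorted brain microglia from mice that carried Spp1-CreER and a tdTomato reporter, in which a cell that had expressed Spp1 while the recombinase was active kept the red label (Tdt+). Mice had a stroke as neonates, and microglia were sorted from the injured cortex and from the contralateral cortex. Libraries were made with a modified SMART-Seq2 protocol, a plate-based full-length method for few cells. Of 60 samples listed, 52 bulk RNA libraries were analysed. The 6 ATAC libraries and 2 single-cell pools were not analysed here.

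Per the submitters' processing notes, reads were trimmed with cutadapt 2.10, aligned with STAR 2.7.5c and quantified with RSEM 1.3.3 on GRCm38, and edgeR 3.32.0 was part of their downstream work. The 4 deposited tables hold TPM, a length-corrected abundance of transcripts, for 55413 gene symbols each. TPM is scaled to a fixed total in each library, so the tables keep no read depth. Depth per library is therefore unknown here, and no interval or detection limit that needs it is given. There were 7 columns that were matched to no listed sample, 4 of them in the day 28 table and 3 in the day 7 table, and they were not used. By their names they hold Tdt+ cells of the contralateral cortex, as a second contralateral column of each replicate number.

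Groups came from the sample labels. The day 7 table held 3 contralateral, 3 Tdt- and 3 Tdt+ libraries. The day 28 table and the table of day 28 after lipopolysaccharide (LPS) held 4 of each. The time course table held Tdt+ libraries only, 5 each of days 3, 7 and 14 and 4 of day 28. Days 3, 7, 14 and 28 after injury are postnatal days 9, 13, 20 and 34. Contralateral libraries were read as Tdt- cells of that side from the column names, which the labels do not state. At day 7 and day 28 this was a choice, since each number also had a Tdt+ contralateral column. The Tdt- column was taken because the contralateral samples of the LPS table have Tdt- columns only. The labels also do not state the dose or timing of LPS, or whether equal replicate numbers are samples of the same animal.

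The groups, the comparisons, the gene lists, the thresholds and most of the other settings were fixed before the data were examined. That design allowed for a count model. Since the tables hold TPM, its fallback was used, limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with an intensity trend in the variance prior. Genes were tested where TPM was at least 1 in as many libraries as the smallest group of the table. All groups of a table entered the same fit. p-values were adjusted by Benjamini and Hochberg over all genes tested in the table, and 0.05 was the threshold. The 3 interactions joined 2 tables each, as planned, although the tables were normalized separately; a shift common to all groups of a table cancels in an interaction. Levels in different tables were otherwise not tested. Errors of log2 folds are standard errors of the fit, and errors of TPM are SD between libraries. The p-values measure spread between samples, because the labels do not say that samples are separate animals.

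The 24 gene lists held 388 genes: disease-associated microglia (DAM), homeostatic microglia, cell cycle, type I interferon response, inflammatory mediators and NF-kB targets, lipid handling, cholesterol biosynthesis, lysosome, MHC class I, MHC class II, complement, glycolysis, oxidative phosphorylation, immediate early genes, and markers of border-associated macrophages, monocytes, neutrophils, T and NK cells, B cells, neurons, astrocytes, oligodendrocytes, endothelium and erythroid cells. Lists with at least 3 tested genes were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Each such test was repeated with the correlation between genes estimated from the data, with fry, and with a replicate block. Gene positions are those of GRCm38.

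Genes are named in the text by a rule. Spp1 is given in every comparison of groups. Each list contributes up to 4 members, the 2 largest rises and 2 largest falls that passed, or the 2 smallest p-values where none did. Beyond the lists, the largest rises and falls among passed genes with a mean of at least 10 TPM in the higher group and groups that did not overlap are named, up to 8 in each direction, and 5 for time steps and interactions. Predicted, mitochondrial, ribosomal and immunoglobulin or T cell receptor genes were left out there, and genes listed at 0 in a whole group are given no fold. Some genes at the bottom of the rule are left out of the text, and a few others that the rule names are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

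Whether replicate numbers pair samples was checked from the correlation of residuals, with a minimum of 0.1 for every pair set before the fits were compared. After LPS the pairs of Tdt+ and contralateral libraries correlated at 0.194 to 0.551 and those of Tdt+ and Tdt- libraries at 0.123 to 0.524, so values with a replicate block are printed beside results of these 2 comparisons where the block changed a call or moved a count by over 1.5 times. Tdt- and contralateral libraries after LPS correlated at 0.0741 to 0.563. Pairs reached 0.0328 to 0.166 at day 7, -0.00835 to 0.187 at day 28 and -0.0314 to 0.0556 in the time course, and were not treated as paired. In each comparison 5 or 6 of 6 libraries at day 7 and 6 to 8 of 8 at day 28 correlated best with their own number. In the time course at most 3 of 9 or 10 did. Sex transcripts also followed the numbers at day 7 and day 28. These values argue for pairing by number at these 2 days, but not every pair reached the set minimum and the labels do not state it. Fits without the block therefore stay the main ones there, and results with the block are mostly given with the other settings.

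The other settings tried were quantile normalization, no filter on low values, a minimum of 10 TPM, a fit of only the groups compared, a pseudocount of 0.1, a minimum absolute log2 fold of 1, the replicate block, the other gene list tests, and leaving out each library in turn. Chosen after seeing the data were the omission of the LPS libraries numbered 4 with and without the block, quantile normalization together with the block, and the Xist level as a covariate in the time course. Count-model alternatives were not run, since they need counts. The fit was tested on simulated data in which 100 genes changed by log2 1 and 100 by log2 2 at the same time. The changed genes were drawn from those with a mean level above 10 TPM, and noise was drawn independently for each gene. The shares recovered therefore do not hold for lower genes, and they can be smaller where few genes change. Of changes of log2 1 it recovered 25% in the day 7 comparison of Tdt+ with contralateral libraries, 63% at day 28, 52% after LPS, 64% from day 3 to day 7 and 24% in the LPS interaction. For changes of log2 2 these shares were 80%, 93%, 94%, 96% and 83%. Each simulation also called 7 to 10 genes that had not been changed. Random numbers had fixed seeds. Figures were drawn with matplotlib 3.10.9.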

Results

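Bulk RNA was measured in 52 libraries of sorted microglia in 4 tables. At day 7 after neonatal stroke 3 libraries each were made from contralateral microglia, from Tdt- microglia of the injured cortex and from Tdt+ microglia of the injured cortex. At day 28 there were 4 libraries of each group, and after LPS at day 28 another 4 of each. The time course held Tdt+ libraries of day 3 (n = 5), day 7 (n = 5), day 14 (n = 5) and day 28 (n = 4). Between 11544 and 14093 genes reached 1 TPM in a library, and read depth is unknown because TPM keeps none of it. TPM is given as mean ± SD between libraries and log2 folds as estimate ± SE of the limma fit.

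Spp1, the gene whose expression history the label records, lies on chromosome 5 at 104435111 to 104441053 of GRCm38 and encodes the secreted phosphoprotein osteopontin. At day 7 it averaged 35.3 ± 29.7 TPM in contralateral, 133 ± 104 in Tdt- and 766 ± 205 in Tdt+ libraries (n = 3 each). At day 28 the means were 1.97 ± 0.731, 3.86 ± 2.59 and 10.9 ± 14.24 TPM in the same order (n = 4 each), where Tdt+ replicate 1 held 31.74 TPM and the other 3 Tdt+ libraries 1.3 to 8.45 TPM. After LPS they were 77.5 ± 53.6, 180 ± 130 and 280 ± 259 TPM (n = 4 each). The LPS libraries numbered 4 held 157, 373 and 665 TPM in this order, and the others 42.9 to 57.3, 98.3 to 145 and 118 to 192 TPM. In the time course Tdt+ libraries held 33.2 ± 17.6 TPM at day 3, 0.824 ± 0.969 at day 7, 0.71 ± 1.25 at day 14 and 0.993 ± 1.60 at day 28, with 2.89 TPM in day 14 replicate 2 (others at most 0.66) and 3.36 TPM in day 28 replicate 3 (others at most 0.61). Levels in different tables were not tested, since the tables were normalized separately.

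**Figure D1:**
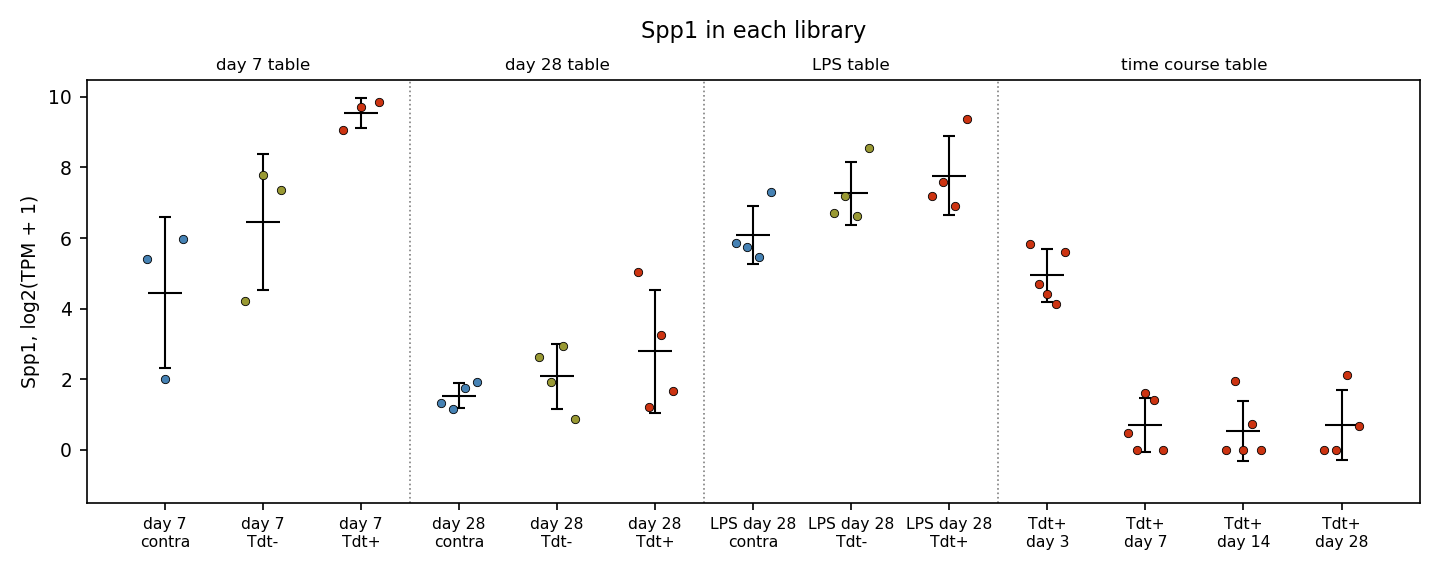
Spp1 as log2(TPM + 1) in each library (points) of the 13 groups, with dotted lines between the 4 tables and dashes and bars for mean ± SD. Tdt+ libraries averaged 766 TPM in the day 7 table and 0.824 TPM at day 7 of the time course.

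At day 7, Tdt+ and contralateral microglia were compared to ask how cells with Spp1 history in the injured cortex differ from cells of the uninjured side. Apoe, the lipid carrier induced in disease-associated microglia, was higher in Tdt+ libraries by log2 1.66 ± 0.17 (53720 ± 8018 against 16910 ± 1958 TPM, n = 3 each, adjusted p 0.0058). Ccl12, a chemokine for monocytes, was higher by 2.21 ± 0.20 (2560 ± 360 against 569 ± 174 TPM, adjusted p 0.00348). The complement gene C4b was higher by 3.48 ± 0.39 (adjusted p 0.00753) and fibronectin, Fn1, by 4.70 ± 0.61 (43.5 ± 23.2 against 0.58 ± 0.57 TPM, adjusted p 0.0197). Gpx3, a secreted peroxidase, was higher by 1.72 (adjusted p 0.0431), and Tspo, the mitochondrial protein used as an imaging marker of reactive microglia, by 1.23 ± 0.17 (adjusted p 0.0269). Crybb1, a gene of immature microglia, was lower by 0.94 ± 0.14 (239 against 461 TPM, adjusted p 0.0431), and the sialomucin Cd164 was lower by 0.73 ± 0.11 (adjusted p 0.0431). In each of these genes all 3 Tdt+ libraries lay on the same side of all 3 contralateral libraries. For Gpx3, Tspo and Cd164, which are on no list, this was a condition of being named. Spp1 itself was listed at log2 5.09 ± 1.02 and did not pass (adjusted p 0.148).

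Of 12637 genes tested at day 7, 9 differed between Tdt+ and contralateral libraries, 7 higher and 2 lower, and 907 had an unadjusted p below 0.05. The gene not yet named was the predicted gene Gm23094 (adjusted p 0.0155), listed at 0 in contralateral libraries and given after its value was seen. The count was 5 without contralateral replicate 1, 4 without contralateral replicate 2, 22 without contralateral replicate 3, 3 without Tdt+ replicate 1, 3 without Tdt+ replicate 2 and 4 without Tdt+ replicate 3. Without a filter 3 genes passed, and with a minimum of 10 TPM 16 did. With the replicate block 27 did, 19 higher and 8 lower, though numbers were not treated as pairs here.

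Among 29 DAM genes 1 was higher (Apoe) and 28 did not pass; 3 passed when adjusted over the list alone. The list median was log2 0.23 with a camera adjusted p of 0.000711, and the adjusted p was 0.137 with estimated correlation. Of 24 homeostatic genes 1 was lower (Crybb1), 8 were lower over the list alone, and the median was -0.36 (camera adjusted p 8.28e-10, estimated correlation adjusted p 0.167). None of 25 interferon genes passed over all genes and 3 were higher over the list alone, with Ifi204 at 1.68 (adjusted p 0.0614) and a median of 0.70 (camera adjusted p 4e-06, estimated correlation adjusted p 0.177). Of 23 inflammatory genes 1 was higher (Ccl12), and 3 were higher and 1 lower over the list alone (median 0.39, camera adjusted p 0.000818, estimated correlation adjusted p 0.2). None of 20 lipid handling genes passed, 3 were higher over the list alone, and the median was 0.67 (camera adjusted p 6.84e-05, estimated correlation adjusted p 0.137). None of 25 cell cycle genes passed and their median was 0.71 (camera adjusted p 0.000482, estimated correlation adjusted p 0.35). Of 12 complement genes 1 was higher (C4b), also over the list alone (median 0.50, camera adjusted p 0.000444, estimated correlation adjusted p 0.114).

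Of 4 monocyte markers 1 was higher (Fn1), and 2 were higher and 1 lower over the list alone (median 1.36, camera adjusted p 0.00209, estimated correlation adjusted p 0.137). None of 6 MHC class II genes passed and Cd74 was lower over the list alone, with a median of -0.44 (camera adjusted p 0.00942, estimated correlation adjusted p 0.137). Lysosome genes had a median of 0.07 (camera adjusted p 0.0373, estimated correlation adjusted p 0.137), and glycolysis genes of 0.17 (camera adjusted p 0.025, estimated correlation adjusted p 0.376), with none passed. No gene passed and no camera call was made for cholesterol biosynthesis (median 0.13, adjusted p 0.594), MHC class I (0.12, 0.139, quantile normalization 0.0339), immediate early genes (-0.08, 0.338), border-associated macrophages (0.68, 0.13), oligodendrocytes (0.11, 0.524) or endothelium (-0.18, 0.139). Oxidative phosphorylation had a median of -0.07 and a mean above 0, with a camera adjusted p of 0.705 and 1 gene higher over the list alone. Neutrophil, B cell and astrocyte markers had 2 tested genes each and T and NK cell, neuron and erythroid markers had 0, so these lists had no set test.

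Tdt+ and Tdt- microglia of the injured cortex were compared at day 7 to part Spp1 history from injury. Spp1 was listed at log2 3.09 ± 1.02 (adjusted p 0.862), Apoe at 0.97 ± 0.17 (53720 ± 8018 against 27850 ± 7212 TPM, n = 3 each, adjusted p 0.425), C4b at 1.86 (adjusted p 0.532) and Ccl12 at 0.92 (adjusted p 0.597), and none of these passed. The 2 genes that passed, Gm37401 (adjusted p 0.0035) and Gm23094 (adjusted p 0.0309), are predicted genes listed at 0 in Tdt- libraries and are named after their values were seen, and 662 genes had an unadjusted p below 0.05. The count was 1 without Tdt- replicate 1 or 2 and 6 without Tdt- replicate 3, whose neutrophil marker score was 3.37 against 0.885 and 0.938 in the other Tdt- libraries. Homeostatic genes were lower as a list (median -0.35, 1 lower over the list alone, camera adjusted p 7.7e-08, estimated correlation adjusted p 0.393). DAM genes were higher (median 0.09, 1 over the list alone, camera adjusted p 0.0151, estimated correlation adjusted p 0.393), as were lipid handling genes (0.16, 0.0151 and 0.393) and complement genes (0.23, 1 over the list alone, 0.0151 and 0.385). Cell cycle genes were also higher (0.38, camera adjusted p 0.0298, estimated correlation adjusted p 0.671). Inflammatory genes had a median of -0.01 and a mean of 0.22, with a camera adjusted p of 0.14.

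Tdt- and contralateral microglia were compared at day 7 to ask what injury left in cells without the label. Ccl12 was listed at log2 1.29 ± 0.20 (1354 against 569 TPM, n = 3 each, adjusted p 0.319), Spp1 at 2.00 ± 1.02 (adjusted p 0.905), Apoe at 0.69 (adjusted p 0.642) and Fn1 at 2.74 (adjusted p 0.554). Only the predicted gene Gm37401, listed at 0 in Tdt- libraries and named after its value was seen, passed (adjusted p 0.0059), and 718 genes had an unadjusted p below 0.05. The count was 0 without Tdt- replicate 2, 2 without contralateral replicate 2, 4 without contralateral replicate 3 or Tdt- replicate 1 and 5 without Tdt- replicate 3, the library with the high neutrophil marker score. Interferon genes were higher as a list (median 0.56, 1 over the list alone, camera adjusted p 0.00954, estimated correlation adjusted p 0.499), and so were MHC class I genes (0.29, camera adjusted p 0.00954, estimated correlation adjusted p 0.499). Of the monocyte markers 2 were higher over the list alone, with a camera adjusted p of 0.0566. With quantile normalization monocyte, inflammatory and glycolysis lists had an adjusted p of 0.045 each, lysosome 0.0477, DAM 0.0478 and lipid handling 0.0493, all higher.

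At day 28 the same groups were compared to ask whether cells with Spp1 history keep a different state after 4 weeks. Apoe was listed higher in Tdt+ than in contralateral libraries by log2 0.73 ± 0.15 (4180 ± 815 against 2517 ± 469 TPM, n = 4 each, adjusted p 0.631). Zbp1, a sensor of nucleic acids induced by interferon, was listed at 2.23 ± 0.49 (5.52 against 0.23 TPM, adjusted p 0.631) and the MHC class I gene H2-Q6 at 1.43 ± 0.30 (20.1 against 6.81 TPM, adjusted p 0.631). C4b was at 2.01 (adjusted p 0.878), the complement regulator Cfp at 1.76 (adjusted p 0.971), Pecam1 at -1.05 (adjusted p 0.631) and Spp1 at 1.25 ± 0.68 (adjusted p 0.991). Of 12710 genes tested with limma 0 differed, and 585 had an unadjusted p below 0.05. Without contralateral replicate 2 or Tdt+ replicate 3 the count was 1.

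Over the list alone 2 of 24 interferon genes were higher in Tdt+ than in contralateral libraries at day 28 (median 0.35, camera adjusted p 0.0027, estimated correlation adjusted p 0.0686). Over their own lists 2 of 14 MHC class I genes were higher (median 0.13, 0.00116 and 0.0612), as were 3 of 11 complement genes (median 0.14, 0.000773 and 0.11) and 1 of 28 DAM genes (median 0.17, 0.00116 and 0.334). With the replicate block and estimated correlation together, complement and DAM genes had a camera adjusted p of 0.0342 each, though numbers were not treated as pairs here. Lysosome genes had a median of 0.11 (camera adjusted p 0.00362, estimated correlation adjusted p 0.352). Of 5 border-associated macrophage markers 1 was lower over the list alone (median -0.39, camera adjusted p 0.0255, estimated correlation adjusted p 0.127), and Pf4 was listed at 0 in Tdt+ libraries. Homeostatic (median 0.06), inflammatory (0.03) and lipid handling genes (0.10) each had a camera adjusted p of 0.615, and cell cycle genes (-0.29) had 0.112.

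Tdt+ and Tdt- libraries at day 28 differed in 0 of the genes tested with limma, and 473 had an unadjusted p below 0.05. Apoe was listed at log2 0.80 ± 0.15 (4180 ± 815 against 2381 ± 286 TPM, n = 4 each, adjusted p 0.667), with all 4 Tdt+ libraries above all 4 Tdt- libraries. Lyz2 was at 0.47 (adjusted p 0.999), the immediate early gene Nr4a1 at -1.83 (adjusted p 0.999) and Spp1 at 0.70 ± 0.68 (adjusted p 0.999), and at -0.05 without Tdt+ replicate 1. As lists, DAM genes were higher (median 0.13, 1 over the list alone, camera adjusted p 9.8e-06, estimated correlation adjusted p 0.471), as were MHC class I genes (0.14, 1 over the list alone, 0.016 and 0.165). With the replicate block and estimated correlation together, DAM genes had a camera adjusted p of 0.00918, though numbers were not treated as pairs at day 28. Interferon genes (0.12, camera adjusted p 0.046, estimated correlation adjusted p 0.276) and lysosome genes (0.06, 0.018 and 0.632) were also higher. Between Tdt- and contralateral libraries 0 genes differed by limma and 575 had an unadjusted p below 0.05. Spp1 was at 0.55 ± 0.68 (adjusted p 0.994), Egr2 was higher over the immediate early list alone (1.68, adjusted p 0.987), and no list had a camera call. The counts of these 2 comparisons were 1 without Tdt+ replicate 3 and without contralateral replicate 2, respectively.

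After LPS, a bacterial product that activates microglia, the same comparison asked whether cells with Spp1 history respond differently to a second challenge. Saa3, an acute-phase amyloid, was higher in Tdt+ than in contralateral libraries by log2 6.88 ± 0.72 (28410 ± 10720 against 394 ± 471 TPM, n = 4 each, adjusted p 0.000495). Fpr1, the receptor for bacterial formyl peptides, was higher by 6.32 ± 0.86 (664 ± 155 against 22.1 ± 36.3 TPM, adjusted p 0.00219), and the scavenger receptor Marco by 6.03 ± 0.95 (1186 ± 314 against 44.9 ± 62.9 TPM, adjusted p 0.00642). Ch25h, which makes 25-hydroxycholesterol, was higher by 6.23 ± 0.73 (adjusted p 0.000982), Acod1, which makes itaconate, by 5.45 ± 0.71 (adjusted p 0.0017), and the lysozyme gene Lyz2 by 2.22 ± 0.29 (1485 ± 367 against 321 ± 87.0 TPM, adjusted p 0.0017). The homeostatic receptor P2ry12 was lower by 1.07 ± 0.19 (806 ± 214 against 1673 ± 294 TPM, adjusted p 0.0135), Selplg by 0.84 ± 0.15 (1484 against 2644 TPM, adjusted p 0.0117) and Tspan13 by 1.26 ± 0.15 (adjusted p 0.000927). In each gene named here the 4 Tdt+ libraries did not overlap the 4 contralateral ones. For Fpr1, Acod1 and Tspan13, which are on no list, this was a condition of being named. Spp1 was at 1.67 ± 0.57 and did not pass (adjusted p 0.244), and its adjusted p was 2.57e-05 with the replicate block and 0.00502 without the libraries numbered 4.

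Of 13397 genes tested after LPS, 181 differed between Tdt+ and contralateral libraries, 120 higher and 61 lower. With the replicate block 930 differed, 323 higher and 607 lower, so the balance of directions changed with the block. The median of all genes was -0.12, and relative to it the rises were larger and the falls smaller by that amount. With quantile normalization the counts were 137 higher and 49 lower. The count was 87 without Tdt+ replicate 1, 77 without contralateral replicate 2, 103 without Tdt+ replicate 3 and 109 without Tdt+ replicate 4. Other large rises were Cxcl13 (5.12), Wfdc21 (4.73), Vnn3 (4.62), Fpr2 (4.52), Lox (4.24) and Cd38 (4.20), with adjusted p from 0.000168 for Lox to 0.00609 for Cxcl13. The lectin Siglecf (-1.39, adjusted p 0.00472), Gadd45g (-1.61, adjusted p 0.0163) and Numb (-1.65, adjusted p 0.0493) were lower.

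**Figure D2:**
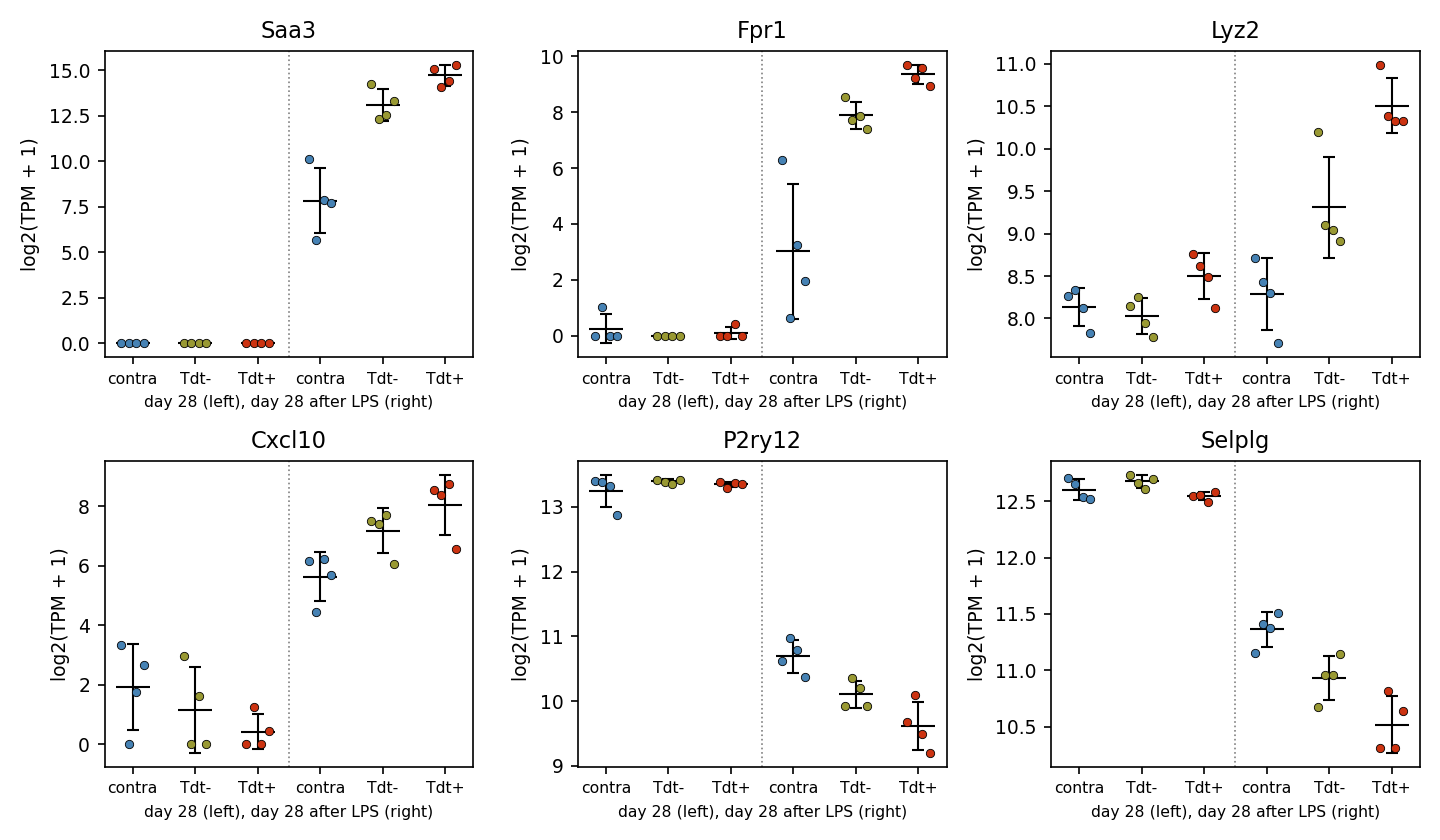
Saa3, Fpr1, Lyz2, Cxcl10, P2ry12 and Selplg as log2(TPM + 1) per library (points), with contralateral, Tdt- and Tdt+ groups at day 28 on the left and after LPS on the right, and dashes and bars for mean ± SD. After LPS, Saa3 averaged 394 TPM in contralateral, 10110 TPM in Tdt- and 28410 TPM in Tdt+ libraries.

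Of 27 inflammatory genes 9 were higher in Tdt+ than in contralateral libraries after LPS and 18 did not pass, 13 were higher over the list alone, and 15 with the block. Their median was 1.22 (camera adjusted p 1.32e-23), and the adjusted p with estimated correlation was 0.0352, and 0.0536 with the block as well. Cd40, which is on the MHC class II list, was higher by 2.37 (adjusted p 0.0356). Of 24 homeostatic genes 4 were lower, 14 over the list alone and 19 with the block (median -0.64, camera adjusted p 1.48e-11, estimated correlation adjusted p 0.138). Of 25 interferon genes 3 were higher, among them Cxcl10 (2.42 ± 0.53, 304 against 54.0 TPM, adjusted p 0.0438) and Rsad2 (2.16, adjusted p 0.034), 4 over the list alone and 11 with the block (median 0.59, camera adjusted p 3.86e-12, estimated correlation adjusted p 0.145). Of 12 complement genes 3 were higher, including C3 (3.48, adjusted p 0.00451) and Cfp (2.47, adjusted p 0.005), and 1 was lower. Over the complement list alone 4 were higher and 1 lower (median 0.31, camera adjusted p 0.00252, estimated correlation adjusted p 0.0685, quantile normalization 0.0629). Of 16 glycolysis genes Pgk1 was higher (0.71, adjusted p 0.0212), 4 over the list alone (median 0.27, camera adjusted p 1.54e-05, estimated correlation adjusted p 0.138). Of 19 lipid handling genes 2 were higher, among them Msr1 (1.44, adjusted p 0.0214), and over the list alone 3 were higher and 3 lower (median 0.39, camera adjusted p 0.00252, estimated correlation adjusted p 0.0836).

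Of 27 DAM genes 2 were higher, including the ferritin gene Fth1 (1.38 ± 0.18, 11720 against 4506 TPM, adjusted p 0.0017), and Cadm1 was lower (-0.84, adjusted p 0.034); over the list alone 8 were higher and 5 lower. The DAM median was -0.04, its mean 0.19 and its camera direction up (adjusted p 0.0948, with the block 0.0458). MHC class I genes had 2 higher over the list alone (median 0.245, camera adjusted p 3.8e-07, estimated correlation adjusted p 0.138), and cholesterol biosynthesis genes had none (0.20, 0.00171 and 0.138). Lysosome genes were at -0.17 (camera adjusted p 0.0948, with the block 0.0393), and with quantile normalization they were lower (0.00587). Of 9 MHC class II genes 1 was higher (Cd40), and 2 were higher and 2 lower over the list alone, with a median of -0.17 against a mean of 0.24 (camera adjusted p 0.387). Of 6 border-associated macrophage markers Ms4a7 was higher (2.12, adjusted p 0.00367), with a median of -0.05, a mean of 0.21 and a camera adjusted p of 0.204. Of 5 monocyte markers Ms4a4c was higher (1.42, adjusted p 0.0472), with a median of -0.28, a mean of 0.44 and a camera adjusted p of 0.0743, and 0.0266 with the block. Cell cycle (median 0.04, camera adjusted p 0.202), immediate early (-0.24, 0.916) and oxidative phosphorylation genes (0.01, 0.0948) had no gene passed.

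Tdt+ and Tdt- libraries of the injured cortex after LPS differed in 0 genes by limma, 618 had an unadjusted p below 0.05, and 62 differed with the replicate block, 40 higher and 22 lower. The chemokine Ccl5 was at log2 1.84 ± 0.50 (1941 ± 922 against 606 ± 440 TPM, n = 4 each, adjusted p 0.688, with the block 0.00549). Lyz2 was at 1.20 ± 0.29 (1485 against 681 TPM, adjusted p 0.451, with the block 0.00549), Cfp at 1.66 (with the block 0.0373), Fth1 at 0.60 (with the block 0.0492) and Crybb1 at -0.76 (with the block 0.0203). Spp1 was at 0.50 ± 0.57 (adjusted p 1, with the block 0.148). The unblocked count was 1 without Tdt+ replicate 1 or Tdt- replicate 2. Inflammatory genes were higher as a list (median 0.415, 2 over the list alone, camera adjusted p 9.43e-08, estimated correlation adjusted p 0.196), and so were interferon genes (0.45, 9.43e-08 and 0.272). Homeostatic genes were lower (-0.34, camera adjusted p 2.14e-06, estimated correlation adjusted p 0.272). MHC class I (0.23, 3.53e-06 and 0.236), glycolysis (0.22, 0.000339 and 0.272), cholesterol biosynthesis (0.18, 0.00332 and 0.196), complement (0.11, 0.0191 and 0.196, quantile normalization 0.0675) and lipid handling genes (0.30, 0.0268 and 0.196) were higher. DAM genes were at -0.09 (camera adjusted p 0.877), and MHC class II genes at -0.36 (camera adjusted p 0.161, with the block 0.0323).

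Tdt- and contralateral libraries after LPS differed in 2 of the genes tested, Saa3 (5.27 ± 0.72, 10110 ± 6466 against 394 ± 471 TPM, n = 4 each, adjusted p 0.0416) and Lox (2.698 ± 0.33, adjusted p 0.0296), which crosslinks collagen; Lox is named here after its value was seen. Ch25h was at 4.70 (adjusted p 0.0549) and Spp1 at 1.18 ± 0.57 (adjusted p 0.874), and 770 genes had an unadjusted p below 0.05. The count was 25 without contralateral replicate 1, 4 without contralateral replicate 4, 1 without contralateral replicate 3 and 0 without Tdt- replicate 1, 3 or 4. It was 0 with a pseudocount of 0.1, 1 without a filter, which was neither Saa3 nor Lox, 8 with at least 10 TPM and 11 with quantile normalization. With the replicate block it was 119, 86 higher and 33 lower. The lowest correlation of a pair here, 0.0741, was below the set minimum, while Tdt+ libraries paired by number with both of these groups. The median of all genes was -0.10. Of 27 inflammatory genes Saa3 was higher, 7 over the list alone (median 0.72, camera adjusted p 3.19e-17, estimated correlation adjusted p 0.0465). Of the monocyte markers 2 were higher over the list alone (median 1.17, camera adjusted p 0.000104, estimated correlation adjusted p 0.0382). Homeostatic genes were lower (-0.35, camera adjusted p 6.1e-06, estimated correlation adjusted p 0.238), as were lysosome genes (-0.20, 0.000817 and 0.14). Interferon (0.17, 0.000331 and 0.467), MHC class II (0.51, 0.0162 and 0.14), cell cycle (0.20, 0.0162 and 0.168), DAM (0.08, 0.0188 and 0.135), oxidative phosphorylation (0.06, 0.000399 and 0.14) and glycolysis genes (0.06, 0.0342 and 0.467) were higher, each with its camera and estimated correlation adjusted p. With quantile normalization the calls of MHC class II (0.0786), DAM (0.176) and glycolysis genes (0.153) were lost.

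**Figure D3:**
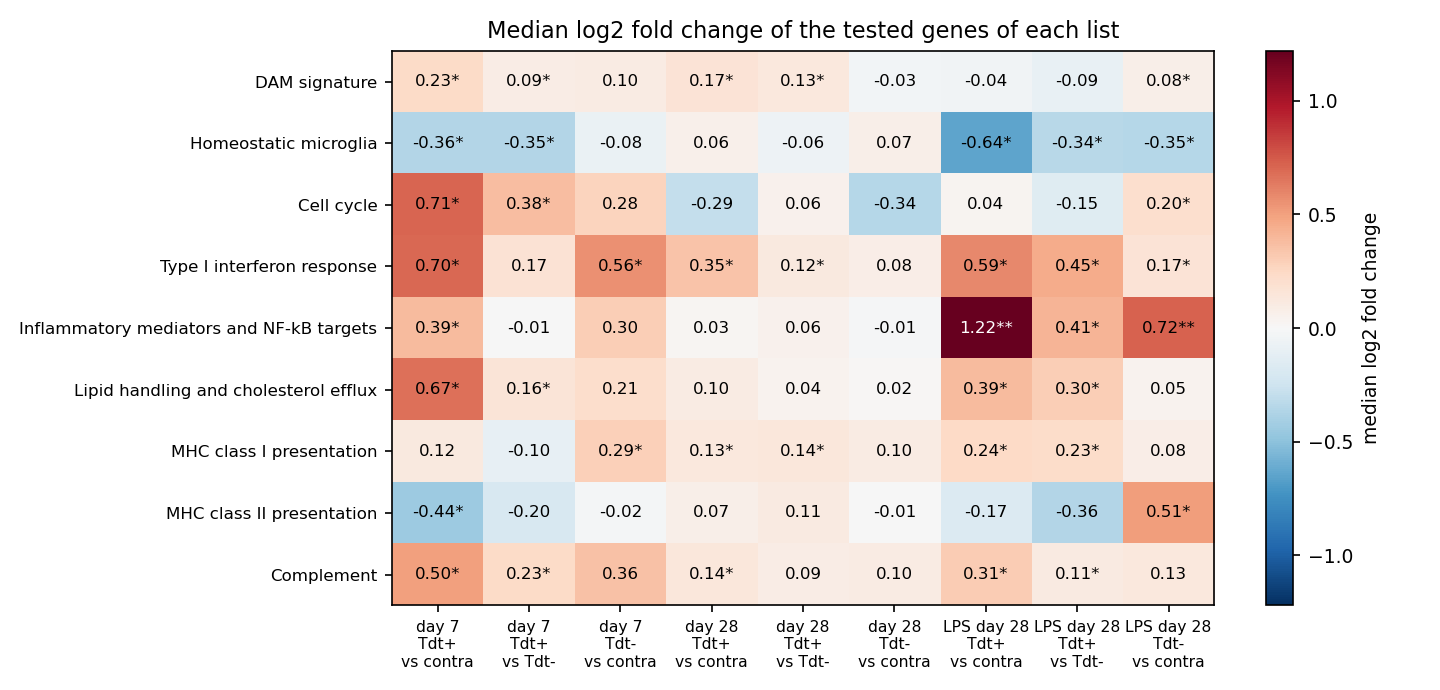
Median log2 fold of the tested genes of 9 lists (cells) in the 9 comparisons within the day 7, day 28 and LPS tables, where * stands for a camera adjusted p below 0.05 and ** for the same with estimated correlation as well. Among these 9 only the inflammatory list has **, at 1.22 for Tdt+ and 0.72 for Tdt- against contralateral libraries after LPS, and with the replicate block as well these had an adjusted p of 0.0536 and 0.115.

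The interaction of LPS with Tdt+ against contralateral, over the day 28 and LPS tables joined, asked whether the difference between these groups depends on LPS. It passed for 81 of 14602 genes, 61 higher and 20 lower, with a median of all genes of -0.12. The count was 50 without LPS Tdt+ replicate 1, 44 without LPS contralateral replicate 2 and 131 without the LPS libraries numbered 4. With the replicate block it was 360, 148 higher and 212 lower, so the balance of directions changed with the block. That block also took numbers as pairs at day 28, where the set minimum was not reached. Saa3 (adjusted p 3.13e-05) and Marco (adjusted p 0.00361) passed but were listed at 0 in all unchallenged libraries of the day 28 table, so their interactions rest on the LPS table alone and are given no value. Fpr1 had an interaction of log2 6.48 ± 0.94 (adjusted p 0.000888) and Lyz2 of 1.86 ± 0.34 (adjusted p 0.00708). P2ry12 had -1.17 ± 0.23 (adjusted p 0.011); it averaged 806 TPM in Tdt+ and 1673 TPM in contralateral libraries after LPS, and 10420 and 9834 TPM without it. Siglecf (-1.41), Tspan13 (-1.26), Ltc4s (-1.12), Gpr146 (-1.11) and Entpd1 (-1.09) also had negative interactions. Spp1 had 0.42 ± 0.94 (adjusted p 0.971).

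Of 27 inflammatory genes 4 had positive interactions with LPS in Tdt+ against contralateral libraries and 12 over the list alone (median 1.04, camera adjusted p 2.84e-20, estimated correlation adjusted p 0.00324). Of 24 homeostatic genes 3 were negative and 15 over the list alone (median -0.67, camera adjusted p 5.46e-14, estimated correlation adjusted p 0.078). Glycolysis had 4 positive and 1 negative gene over the list alone (median 0.28, 3.13e-05 and 0.078), and lysosome had 2 negative ones (-0.30, 0.00304 and 0.262). Of 8 border-associated macrophage markers Ms4a7, listed at 0 in unchallenged Tdt+ libraries of day 28, was positive (adjusted p 0.0111; list median 0.19, camera adjusted p 0.00937, estimated correlation adjusted p 0.078). Interferon genes (0.27, 1 over the list alone, 0.00704 and 0.447), cell cycle genes (0.23, 0.0187 and 0.18) and oxidative phosphorylation genes (0.09, 0.0161 and 0.18) were positive as lists. Fth1 was positive (1.15, adjusted p 0.00952), with 0.089 under quantile normalization, and the DAM list was at -0.11 (camera adjusted p 0.94).

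The interaction of LPS with Tdt+ against Tdt- passed for 0 genes by limma, with 579 at an unadjusted p below 0.05; it was 1 without LPS Tdt- replicate 1 and 2 without LPS Tdt+ replicate 3. Inflammatory genes were positive (median 0.25, camera adjusted p 0.00027, estimated correlation adjusted p 0.529), homeostatic genes negative (-0.27, 0.000806 and 0.529) and glycolysis genes positive (0.19, 0.0281 and 0.529, quantile normalization 0.084). Spp1 had -0.20 ± 0.94 (adjusted p 0.999). The interaction of day with Tdt+ against contralateral, over the day 7 and day 28 tables, also passed for 0 genes by limma, with 834 at an unadjusted p below 0.05. It was 1 without day 28 contralateral replicate 2, 3 without day 7 contralateral replicate 1, 2 without day 7 contralateral replicate 2 or 3, and 8, 2 and 4 without day 7 Tdt+ replicates 1, 2 and 3. Fn1 had -4.08 (adjusted p 0.196), Selplg 0.71 (adjusted p 0.165) and Spp1 -3.84 ± 1.28 (adjusted p 0.686). Homeostatic genes were positive (0.30, 7 over the list alone, camera adjusted p 8.85e-11, estimated correlation adjusted p 0.163). Negative were cell cycle (-0.69, 2.19e-05 and 0.215), lipid handling (-0.54, 0.00146 and 0.196), inflammatory (-0.44, 0.0254 and 0.215), interferon (-0.40, 0.0254 and 0.382) and monocyte lists (-1.30, 0.0254 and 0.163).

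The time course asked how Tdt+ cells change after injury. It holds no contralateral or Tdt- libraries, so time since injury and age cannot be told apart. From day 3 to day 7 Spp1 fell by log2 4.24 ± 0.50 (33.2 ± 17.6 to 0.824 ± 0.969 TPM, n = 5 each, adjusted p 5.51e-06). Gpnmb, a glycoprotein of phagocytic microglia, fell by 6.96 ± 0.56 (276 ± 103 to 1.35 ± 1.31 TPM, adjusted p 3.41e-08), and the fatty acid binding gene Fabp5 fell by 4.48. The homeostatic genes Selplg (2.30 ± 0.11, 289 to 1418 TPM, adjusted p 7.84e-12) and Tmem119 (2.23, 392 to 1821 TPM, adjusted p 1.03e-12) rose. The proliferation genes Ube2c and Birc5 fell by 2.19 and 2.06, and Folr2, of border-associated macrophages, fell by 4.40 (111 to 4.44 TPM). For all of these genes the 5 libraries of day 7 did not overlap the 5 of day 3.

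From day 3 to day 7, 2198 of 15316 genes changed, 1521 higher and 677 lower, and 904 and 886 with quantile normalization. With the Xist level as a covariate 1405 genes changed, and Xist averaged 63.0 TPM at day 3 and 128 TPM at day 7. The mitochondrial share was 7.79 to 8.56% in day 3 libraries and 6.05 to 6.81% in day 7 libraries. The median of all genes was 0.18, and relative to it rises were smaller and falls larger by that amount. Outside the lists Il7r (3.02) and Tns1 (2.33) rose, and Wfdc17 (-5.47), Ms4a4a (-5.12), Colec12 (-4.15) and Lgals1 (-3.73) fell. Of 30 DAM genes 1 rose (Timp2, 0.47, adjusted p 0.0437, and 0.249 with quantile normalization), 23 fell and 6 did not pass, with 25 falls over the list alone (median -0.94, camera adjusted p 1.12e-33, estimated correlation adjusted p 2.29e-05). Of 24 homeostatic genes 21 rose and 3 did not pass, 22 over the list alone (0.98, 8.15e-31 and 0.000571). Of 25 cell cycle genes 18 fell, 20 over the list alone (-1.13, 8.82e-17 and 0.0007). Of 8 border-associated macrophage markers 8 fell, among them Ms4a7 by 4.27 (-3.12, 5.46e-16 and 3.03e-05). Of 20 lipid handling genes 3 rose, including Dgat1 (0.68), and 12 fell, including Apoc2 (-3.53) and Pltp (-3.25), with a median of -0.68 (3.26e-10 and 0.000119). Of 20 oxidative phosphorylation genes 9 fell, including Sdhc (-0.92), 13 over the list alone (-0.43, 1.03e-10 and 0.000119). Of 16 glycolysis genes 10 fell, including Pgk1 (-1.26) and Tpi1 (-1.17), and over the list alone 2 rose and 10 fell (-0.68, 1.98e-10 and 0.01).

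Of 25 interferon genes 6 fell from day 3 to day 7, including Slfn5 (-2.39) and Ifi27l2a (-1.98), and 14 over the list alone (median -0.82, camera adjusted p 1.74e-11, estimated correlation adjusted p 0.0796). Of 25 lysosome genes 4 rose, including Man2b1 (0.47), and 10 fell, including Gla (-1.92), with a median of -0.25 (4.62e-05 and 0.0796). Of 15 MHC class I genes 5 rose, including H2-Q6 (2.21; list median 0.32, 0.0167 and 0.301), and of 9 MHC class II genes 5 rose, including H2-Eb1 (2.22; list median 0.63, 0.0145 and 0.0669), with 6 over the list alone. Of 23 inflammatory genes 5 rose, including Il1a (1.20), and 3 fell, including Il1rn (-2.37), without a camera call (adjusted p 0.341). Of 12 complement genes 3 rose, including Itgam (0.64), and 2 fell, C3ar1 (-1.47) and C5ar1 (-0.98; camera adjusted p 0.326). Of 15 immediate early genes 4 rose, including Junb (1.40; camera adjusted p 0.343), and none of 19 cholesterol biosynthesis genes changed (adjusted p 0.326; median 0.04, mean below 0). Of 6 monocyte markers Fn1 fell (-2.37; camera adjusted p 0.326). Tubb3 (-1.29) fell among 3 neuron markers (median -0.996, camera adjusted p 0.0117, estimated correlation adjusted p 0.0796).

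Among 7 astrocyte markers Slc1a3 rose (1.09) and Gfap fell (-1.42) from day 3 to day 7 (camera adjusted p 0.305). Mbp (0.90) and Mag (0.69) rose among 6 oligodendrocyte markers (camera adjusted p 0.447), and Pecam1 (1.76) among 4 endothelial markers (camera adjusted p 0.324). None of 3 B cell markers changed (camera adjusted p 0.549). Both tested neutrophil markers, Cxcr2 (1.01) and Csf3r (0.43), rose, as did Alas2 (2.06), the only tested erythroid marker. The only tested T and NK cell marker did not change. These 3 lists had too few tested genes for a set test.

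**Figure D4:**
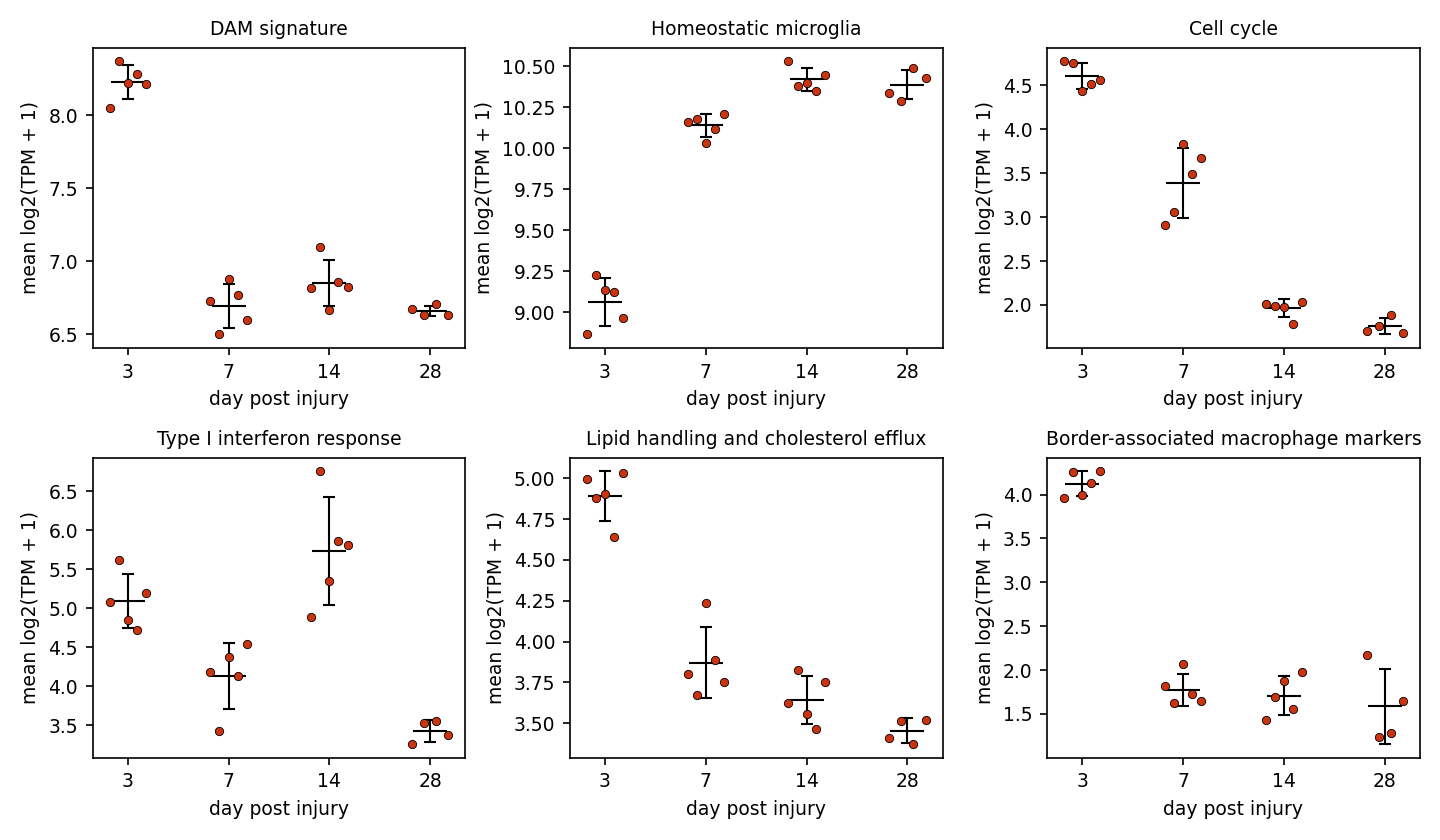
Score of 6 lists (mean log2(TPM + 1) of their genes) in each Tdt+ library (points) by day after injury, with dashes and bars for mean ± SD. From day 3 to day 7 the DAM list fell with a median of log2 -0.94 and the homeostatic list rose with 0.98; from day 14 to day 28 the homeostatic median was -0.03, with the camera direction up under quantile normalization.

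From day 7 to day 14 Apoe fell by log2 1.92 ± 0.17 (21640 to 5487 TPM, n = 5 each, adjusted p 2.02e-06) and the growth factor gene Igf1 by 1.54. Ifit3, induced by interferon, rose by 2.72 ± 0.33 (26.8 to 192 TPM, adjusted p 4.36e-05) and Ifit1 by 2.66. Selplg rose by 1.15 (1418 to 3136 TPM), and Ube2c and Top2a fell by 3.04 and 2.67. Spp1 was at -0.16 ± 0.50 (adjusted p 0.91). The mitochondrial share was 6.05 to 6.81% in day 7 and 4.71 to 5.24% in day 14 libraries. In all, 919 genes changed, 683 higher and 236 lower, and 367 and 317 with quantile normalization; the median of all genes was 0.14. Sex transcripts shifted with day, with Xist at -6.54 and Ddx3y at 3.02, and with the Xist level as a covariate 4 genes passed. Day and the sex makeup of the libraries were therefore not separated in this step. Outside the lists B3gnt2 rose (3.70) and Gpx3 fell (-3.32).

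Of 25 interferon genes 17 rose from day 7 to day 14, 23 over the list alone (median 1.55, camera adjusted p 7.75e-18, estimated correlation adjusted p 0.0735). Day 14 replicate 2, the library with an erythroid score of 5.02 (others of its day at most 0.480), had the highest interferon score, 6.75; the other day 14 libraries scored 4.89 to 5.86 and the day 7 libraries 3.43 to 4.54. Without this replicate Ifit3 was at 2.46 (adjusted p 0.000133). Of the cell cycle genes 15 fell, 19 over the list alone (-1.55, 7.1e-24 and 0.000586). Of the DAM genes 8 rose, including Cst7 (1.40) and Ccl6 (1.21), and 3 fell, with 15 and 6 over the list alone (0.24, camera adjusted p 0.153, and 0.000963 with quantile normalization). Of the homeostatic genes 6 rose, including Cst3 (0.85), and 12 over the list alone (0.30, 0.00017 and 0.196). Of the inflammatory genes 4 rose, including Ccl4 (3.48, 10.5 to 90.2 TPM) and Il6 (2.21), and 7 over the list alone (0.56, 0.000184 and 0.0766). MHC class I had 4 rises, including H2-T23 (1.28), and 10 over the list alone (0.48, 1.55e-06 and 0.0735), and MHC class II 2, including H2-DMa (1.04), and 3 over the list alone (0.79, 0.00887 and 0.0735). Lysosome genes had 6 rises, and 9 over the list alone (0.21, 0.00165 and 0.196). Complement had 4 rises, including C5ar1 (1.36; camera adjusted p 0.0552, quantile normalization 0.0147). Glycolysis had 4 rises, including Slc16a3 (1.14), and 7 over the list alone (0.33, 0.00932 and 0.261, quantile normalization 0.0662).

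Immediate early genes had 3 rises from day 7 to day 14, including Rhob (1.61), and 4 over the list alone (median 0.67, camera adjusted p 0.00711, estimated correlation adjusted p 0.122). Lipid handling genes had 2 falls, Apoc1 (-3.64) and Abca1 (-0.53; list median -0.13, camera adjusted p 0.00932, estimated correlation adjusted p 0.0735). Sc5d rose (1.34) among the cholesterol biosynthesis genes (camera adjusted p 0.217), and Mrc1 fell (-1.02) among the border-associated macrophage markers (camera adjusted p 0.26). Aldoc (1.80) and Slc1a3 (1.02) rose among the astrocyte markers (camera adjusted p 0.0951, quantile normalization 0.0147).

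From day 14 to day 28 genes of the interferon response fell. Cxcl10 fell by log2 3.68 (70.0 to 7.85 TPM, n = 5 and 4), Ifit1 by 3.17 (41.3 to 3.65 TPM, adjusted p 0.000409), and all 25 interferon genes fell (median -2.35, camera adjusted p 2.92e-43, estimated correlation adjusted p 0.00618). Apoe fell by 1.53 (5487 to 1900 TPM, adjusted p 6.06e-05), the antigen-presenting gene H2-D1 by 1.10 and the complement factor Cfb by 3.34. Spp1 was at 0.16 ± 0.53 (adjusted p 0.896), and at -0.02 with quantile normalization. In all, 961 genes changed, 622 higher and 339 lower, and 371 and 428 with quantile normalization; the median of all genes was 0.18. The mitochondrial share was 4.71 to 5.24% in day 14 and 3.24 to 3.65% in day 28 libraries, and day 14 replicate 2 again had the highest interferon score (6.75) with the erythroid score of 5.02; the day 28 libraries scored 3.26 to 3.55 for interferon. The count was 622 without day 14 replicate 4, 493 without day 28 replicate 2 and 506 without day 28 replicate 3, and 438 when only these groups were fitted.

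MHC class I had 6 falls from day 14 to day 28, including Tap1 (-0.94), and 9 over the list alone (median -0.68, camera adjusted p 5.24e-14, estimated correlation adjusted p 0.00618). Inflammatory genes had 4 falls, including Ccl12 (-2.07) and Ccl2 (-1.79), and 1 rise and 7 falls over the list alone (-0.43, 4.04e-06 and 0.0309). MHC class II had 2 falls over the list alone (-0.58, 0.00223 and 0.0309), and oxidative phosphorylation 1 fall, Cox4i1 (-0.54; list median -0.19, 4.03e-05 and 0.00784). DAM genes had 4 falls, including Igf1 (-1.26), with a median of -0.09 (camera adjusted p 0.000281, estimated correlation adjusted p 0.0768, quantile normalization 0.694). Homeostatic genes had 4 falls, including Crybb1 (-1.22) and Tmem119 (-0.59), with a median of -0.03 (camera down, adjusted p 0.0277, estimated correlation adjusted p 0.445), and with quantile normalization the direction was up (0.00437). Complement had 4 falls, including C4b (-1.496), and 5 over the list alone (-0.35, 0.000107 and 0.0768, quantile normalization 0.1). Lysosome had 3 falls, including Psap (-0.63) and Ctss (-0.47), and 6 over the list alone (-0.09, 4.03e-05 and 0.0924, quantile normalization 0.694). Cell cycle had 1 fall, Stmn1 (-1.04; list median -0.14, 0.0125 and 0.254), and monocyte markers none (-0.77, 0.0133 and 0.0975). Outside the lists Ndufc1 (2.60) and Tgm2 (1.93) rose, and Evi2b (-3.55), Adam33 (-3.16) and Helz2 (-2.94) fell.

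Between day 3 and day 28 Spp1 fell by log2 4.24 ± 0.53 (33.2 to 0.993 TPM, n = 5 and 4, adjusted p 2.52e-06), Gpnmb by 7.51 and Igf1 by 6.49, while Selplg (3.24) and Tmem119 (2.48) rose. Of the genes tested 6681 changed, 5460 higher and 1221 lower, and 2021 and 2026 with quantile normalization. With the Xist level as a covariate 4070 changed, and Xist averaged 63.0 TPM at day 3 and 0 at day 28. The mitochondrial share was 7.79 to 8.56% in day 3 and 3.24 to 3.65% in day 28 libraries, and the ribosomal protein share 10.11 to 10.77% and 3.44 to 3.99%. The median of all genes was 0.56, and relative to it rises were smaller and falls larger by that amount. DAM genes had 4 rises, including Cst7 (1.25, quantile normalization adjusted p 0.12), and 19 falls (median -1.06, camera adjusted p 5.68e-17, estimated correlation adjusted p 0.000263). Homeostatic genes had 21 rises (1.27, 6.56e-14 and 0.016), cell cycle 22 falls (-2.89, 7.45e-29 and 0.000111) and border-associated macrophage markers 8 falls (-3.27, 3.5e-12 and 0.000111). Interferon genes had 17 falls (-1.71, 5.68e-17 and 0.0372), lipid handling 2 rises and 13 falls (-1.14, 8.54e-11 and 0.000111) and oxidative phosphorylation 11 falls (-0.37, 1.46e-10 and 0.000134). Glycolysis had 5 rises and 8 falls (-0.39, 0.000104 and 0.117) and lysosome 5 rises and 9 falls (-0.22, 0.000133 and 0.121, quantile normalization 0.61). Inflammatory genes had 8 rises, including Il1a (1.56), and 6 falls, including Saa3 (-3.34), with a median of 0.20, a mean of -0.13 and a camera adjusted p of 0.278. Outside the lists Csmd3 (5.26), Il7r (4.79) and Tgm2 (4.76) rose, and Gpx3 (-7.50), Hpse (-5.20) and Ifitm2 (-5.09) fell.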

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

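Of the tests of the 3 patterns below, those of the libraries numbered 4 and of the sex makeup were written before their results were seen and the others after, and the splits of libraries were planned before. Of 288 tests for a library far from the others of its group, 30 found one, where chance finds about 1 in 20, or 14.

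After LPS the libraries numbered 4 stood apart in several measures. The mitochondrial share was 6.88% in the Tdt- library (others 3.41 to 3.96%) and 6.20% in the Tdt+ library (others 3.57 to 4.01%), and it was also high, at 6.62%, in the contralateral library (others 3.66 to 4.19%). The 10 most abundant genes took 16.1% of TPM in the Tdt+ library (others 13.72 to 14.05%). Spp1 was at 157 TPM in contralateral library 4 (others 42.9 to 57.3), 373 in Tdt- library 4 (others 98.3 to 145) and 665 in Tdt+ library 4 (others 118 to 192). Immediate early genes, which respond to stress and dissociation, scored 5.08 in Tdt- library 4 (others 3.55 to 3.73) and 4.48 in Tdt+ library 4 (others 3.61 to 3.71), and contralateral library 4 was at 5.28 (others 3.29 to 3.64). Glycolysis genes scored 7.42 in Tdt- library 4 (others 7.04 to 7.07). In contralateral library 4 the cell cycle score was 1.68 (others 2.05 to 2.07) and the T and NK cell score 0.121 (others 0).

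At day 28 without LPS, lipid handling genes scored 3.67 in contralateral library 2 (others 3.33 to 3.37) and 3.70 in Tdt- library 1 (others 3.36 to 3.38). The complement score was 6.37 in contralateral library 1 (others 6.68 to 6.71). The lysosome score was 8.01 in contralateral library 4 (others 8.32 to 8.36), whose erythroid score was 0.201 (others 0). Tdt+ library 4 had an MHC class I score of 6.66 (others 6.48 to 6.50) and 5.31% ribosomal protein genes (others 3.56 to 3.86%).

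In the time course, day 3 library 2 scored 6.84 for MHC class I (others 6.23 to 6.39) and 3.78 for MHC class II (others 3.25 to 3.38). Day 3 library 3 scored 7.25 for oxidative phosphorylation (others 7.36 to 7.38) and 1.56 for neutrophil markers (others 0.836 to 0.896), and day 3 library 5 scored 0.120 for T and NK cell markers (others 0 to 0.0345). Day 7 library 3 had 12931 genes at 1 TPM (others 13175 to 13251) and a monocyte score of 1.99 (others 1.11 to 1.16), and day 7 library 2 an endothelial score of 1.74 (others 1.55 to 1.59). Day 14 library 2 had Spp1 at 2.89 TPM (others 0 to 0.66) and an erythroid score of 5.02 (others 0 to 0.480), and day 14 library 4 a cell cycle score of 1.78 (others 1.98 to 2.04). In day 28 library 3 the 10 most abundant genes took 19.7% of TPM (others 23.7 to 24.1%).

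Between tables, the difference of Tdt+ from contralateral libraries changed with LPS in 81 genes, and the median interaction of the inflammatory list was log2 1.04. In splits that assigned the libraries of both tables anew, 5 of 100 gave as many genes, the real one included, and the highest other count was 115. The 4 other splits with as many genes kept the LPS groups whole, and so the difference of 181 genes between them, and exchanged unchallenged libraries only. The other 95 gave at most 3 genes, so the share of 5 in 100 does not speak for chance, and it does not exclude it either.

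Other splits of the same libraries also gave counts for each comparison within a table. After LPS the count of 181 for Tdt+ against contralateral libraries was reached by 1 of 35 splits, the real one, and the highest other count was 1. Counts in the time course were reached by 1 of 100 splits each, the real one, with 2198 genes against at most 8 from day 3 to day 7, 919 against 36 from day 7 to day 14, 961 against 615 from day 14 to day 28 and 6681 against 4450 between days 3 and 28. The counts of 0 were reached by all splits, since no count can be lower, so their shares of splits say nothing about chance. These were 35 of 35 splits for each day 28 comparison, with highest other counts of 2 for Tdt+ against contralateral, 1 for Tdt+ against Tdt- and 1 for Tdt- against contralateral libraries, and 35 of 35 for Tdt+ against Tdt- after LPS, with a highest other count of 2. The LPS interaction of Tdt+ against Tdt- had 0 genes, reached by 100 of 100 splits, with a highest other count of 2, and the day interaction had 0, reached by 100 of 100, with 14. Tdt- against contralateral libraries after LPS had 2 genes, reached by 2 of 35 splits, with a highest other count of 2, so chance is not excluded for this count by splits that leave the replicate numbers out of account. At day 7 there were too few splits to decide, with 9 genes against a highest other of 3 for Tdt+ against contralateral, 2 against 3 for Tdt+ against Tdt- and 1 against 2 for Tdt- against contralateral libraries. Splits within pairs after LPS were also too few, with 930 genes against 1 for contralateral and 62 against 1 for Tdt- libraries.

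The first pattern is the higher level of inflammatory genes in Tdt+ than in contralateral microglia after LPS. Without the libraries numbered 4 the list median was log2 1.47 against 1.22 with them, and with quantile normalization it was 1.31, which argue against those libraries and against scaling as its cause. Monocytes or neutrophils in the sort are argued against as the main source by Ly6c2, Ccr2, Chil3, S100a8 and S100a9, whose sum was at most 1.69 TPM in a Tdt+ library and 0 to 4.46 TPM in contralateral ones. Lyz2 and the monocyte marker Ms4a4c (1.42, adjusted p 0.0472) were higher all the same, as was the monocyte list with the block (adjusted p 0.0266), so a small share stays open. The injured hemisphere alone, with no part of Spp1 history, is argued against by scores of the inflammatory list as a whole. In that hemisphere they were 7.355 to 7.53 in Tdt+ and 6.762 to 7.092 in Tdt- libraries, and higher in Tdt+ in 4 of 4 pairs. The list test of this difference had a camera adjusted p of 9.43e-08, and 0.196 with estimated correlation. For single genes the question is left open. With numbers as pairs 62 genes differed and without the pairs 0 did, and the splits within pairs were too few to decide. Homeostatic scores were lower in Tdt+ in 4 of 4 pairs, but the groups overlapped (8.434 to 9.377 in Tdt+ and 8.894 to 9.613 in Tdt-).

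The second pattern is the level of Spp1 in Tdt+ libraries of day 7, 766 TPM in the day 7 table and 0.824 TPM in the time course. A difference of scale is argued against by a median log2 difference of -0.158 over 8450 genes (1st to 99th percentile -3.13 to 3.69), where Spp1 at -8.84 was the lowest. A wrong day label in the time course as the only cause is argued against by its highest Spp1 level, 56.2 TPM. The lowest of the day 7 table was 534 TPM. Spp1 cannot exclude a wrong label beside a difference between the tables, which could keep every day of the time course below that level. Homeostatic scores of Tdt+ libraries also differed, at 9.105 to 9.307 in the day 7 table and 10.03 to 10.21 in the time course. The contralateral (9.326 to 9.783) and Tdt- libraries (9.251 to 9.725) of the day 7 table lay below the time course as well. The tables thus differed in more than Spp1, but these scores cannot tell whether the Tdt+ cells themselves differed in state. Whether the DAM list as a whole was lower cannot be decided. The other DAM genes differed by a median of -0.617 relative to all genes and ranged from -2.60 to 1.93. Of these 24 genes 9 were lower by at least 1 and 3 were higher. The labels do not say whether the tables share the sort or the number of targeted Spp1 alleles, which stays open.

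The third pattern is the loss of DAM genes with the rise of homeostatic genes from day 3 to day 7 of the time course. It rests on the time course alone. Homeostatic scores there were 8.866 to 9.229 at day 3 and 10.03 to 10.21 at day 7, but 9.105 to 9.307 in Tdt+ libraries of the day 7 table. DAM scores were 8.053 to 8.369, 6.501 to 6.879 and 7.269 to 7.805 in the same order. Homeostatic scores of the contralateral and Tdt- libraries of the day 7 table, 9.251 to 9.783, also lay below those of day 7 in the time course. Levels in different tables were not tested. The sex makeup of the libraries is argued against by a DAM median of log2 -0.957 with the Xist level as a covariate, against -0.941 without. Dilution of microglia by other cells at day 3 as the only cause is argued against by 20 of 24 homeostatic genes that differed by more than 2 SE from the common median of 0.981, over a range of 0.11 to 2.30. Border-associated macrophages in the day 3 sort cannot be told apart from a microglial state, since Lyve1 and Cd163 summed to at most 4.2 TPM while Pf4 and Ms4a7 summed to 70.5 to 115 TPM. Age and time since injury are confounded in this table, so no biological explanation was tested.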

How the results depend on the processing

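Alternatives with the LPS libraries numbered 4 left out, quantile normalization together with the replicate block, and Xist as a covariate were chosen after the results were seen. For 267 named genes that passed, 3995 of 4477 alternative values kept direction and side of the threshold, 479 were weaker and 3 reversed, and the cause was not tested unless stated. Depth is unknown, so what it limits was not assessed, and count-model alternatives were not run.

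Without a filter on low values the counts at day 7 were 3 for Tdt+ against contralateral, 1 for Tdt+ against Tdt- and 0 for Tdt- against contralateral libraries. At day 28 they were 1, 2 and 2 in the same order, and 1 for Tdt- against contralateral after LPS and 1 for the LPS interaction of Tdt+ against Tdt-. With at least 10 TPM, fewer genes were tested and the counts were 16 and 1 for Tdt+ against contralateral and Tdt- at day 7, and 8 for Tdt- against contralateral after LPS. With only the groups compared in the fit, Tdt+ against contralateral gave 15 at day 7, 1 at day 28 and 117 after LPS. Tdt- against contralateral at day 7 gave 4, Tdt+ against Tdt- after LPS 1 and day 28 against day 14 438. The interactions gave 1 and 46 for LPS, against Tdt- and contralateral, and 1 for day. Quantile normalization gave 11 for Tdt- against contralateral after LPS and 4047 for day 28 against day 3, and a pseudocount of 0.1 gave 0 for the former. With a minimum log2 fold of 1 the time course counts were 922, 391, 477 and 4283 for the 3 steps and for day 28 against day 3.

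With the replicate block, which takes numbers as pairs, the counts were 27 and 1 for Tdt+ against contralateral and Tdt- at day 7. After LPS they were 930 and 62, and 119 for Tdt- against contralateral, 86 higher and 33 lower, where 3 of 4 pairs passed the minimum correlation and 7 of 8 libraries correlated best with their own number. The interactions gave 4 and 360 for LPS, against Tdt- and contralateral, the latter with 148 higher and 212 lower, and 12 for day. In the 2 paired comparisons the block changed the camera calls of DAM, lysosome, monocyte and MHC class II genes given above and of no other list. With the block and estimated correlation together, calls were lost for inflammatory genes in Tdt+ (0.0536) and Tdt- (0.115) against contralateral after LPS, for monocyte markers in the latter (0.0745), for inflammatory genes from day 14 to day 28 (0.0617) and for interferon genes between days 3 and 28 (0.0561). Calls were made at day 28 for DAM and complement genes in Tdt+ against contralateral (0.0342 each) and for DAM genes in Tdt+ against Tdt- (0.00918), and for MHC class II from day 3 to day 7 (0.0378). The same held for homeostatic and glycolysis genes in the LPS interaction against contralateral (0.0056 each) and for homeostatic (0.0367) and cell cycle genes (0.0152) in the day interaction. Without the LPS libraries numbered 4 the counts after LPS were 333 for Tdt+ against contralateral, 3 against Tdt- and 5 for Tdt- against contralateral, and 131 for the LPS interaction against contralateral. With the block as well they were 642, 10 and 84, and with quantile normalization and the block 832, 52 and 125. With Xist as a covariate the time course gave 1405 from day 3 to day 7, 4 from day 7 to day 14 and 4070 between days 3 and 28. Of 118 camera calls of gene lists 24 were kept with estimated correlation, and fry made 67 calls, 51 of them shared.

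Leaving out single libraries gave 3 to 22 genes for Tdt+ against contralateral at day 7, 1 to 6 for Tdt+ against Tdt- and 0 to 5 for Tdt- against contralateral. At day 28 each comparison gave 0 to 1. After LPS the counts were 77 to 193 for Tdt+ against contralateral, and were 0 to 1 against Tdt- and 0 to 25 for Tdt- against contralateral. The interactions gave 0 to 2 and 44 to 104 for LPS, against Tdt- and contralateral, and 0 to 8 for day, and day 28 against day 14 gave 493 to 1070.

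Values that changed sign were mostly of Spp1 where it had not passed. Without 1 library it was -0.0477 (Tdt+ 1) to 1.23 (Tdt+ 2) for Tdt+ against Tdt- at day 28, and -0.0411 (Tdt+ 4) to 0.92 (Tdt- 4) after LPS. From day 7 to day 14 it was -0.52 (day 14 library 2) to 0.0626 (day 7 library 3), with 0.01 for day 7 library 4, and from day 14 to day 28 -0.31 (day 28 library 3) to 0.52 (day 14 library 2), and -0.0223 with quantile normalization. The LPS interaction of Spp1 was -0.74 (LPS Tdt+ 4), 0.09 (LPS Tdt+ 3), 0.22 (LPS Tdt- 4), 0.54 (day 28 Tdt+ 1) and 0.20 (day 28 Tdt- 4) against Tdt-, and -0.11 (LPS Tdt+ 4), -0.10 (day 28 Tdt+ 2) and up to 1.17 (day 28 Tdt+ 1) against contralateral. With Xist as a covariate, from day 7 to day 14 Cnp was -0.00926, Ddx3y -0.84, Tsix 1.32 and Xist itself 4.358e-15 by construction.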

Other observations

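This part gives values and holds no test of significance, and the comparison of the 2 day 7 sets was chosen after the results were seen. The homeostatic receptor gene P2ry12 was listed at 9834 TPM in contralateral and 10420 TPM in Tdt+ libraries of day 28 without LPS, and at 1673 and 806 TPM with it. Levels across tables were not tested. The mitochondrial share in the time course was 8.26 ± 0.283% at day 3, 6.32 ± 0.304% at day 7, 4.91 ± 0.214% at day 14 and 3.38 ± 0.184% at day 28 (n = 5, 5, 5 and 4). Ribosomal protein genes took 10.5 ± 0.240% of TPM at day 3 and 3.79 ± 0.25% at day 28.

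Among DAM genes, the 2 sets of Tdt+ libraries at day 7 differed in both directions. Relative to all genes, Lgals3 was lower in the time course by log2 2.60, Cd83 by 2.05, Gpnmb by 1.67 and Cst7 by 1.63. Lpl, a lipase of disease-associated microglia, was higher by 1.93, Axl by 1.3 and Timp2 by 1.25. Of 24 DAM genes compared, 9 were lower by at least 1 and 3 were higher. These tables were normalized separately and their levels were not tested.

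Sex transcripts followed the replicate numbers. Each number had the same pattern of Xist and Ddx3y in all groups of its table, for 3 of 3 numbers at day 7, 4 of 4 at day 28 and 4 of 4 after LPS. In the time course Xist, on the X chromosome at 103460373 to 103483233, averaged 63.0 ± 78.3 TPM at day 3, 128 ± 70.2 at day 7, 0.0380 ± 0.0531 at day 14 and 0 at day 28. Ddx3y, on the Y chromosome at 1260715 to 1286628, averaged 7.55 ± 6.45, 4.15 ± 5.33, 25.7 ± 10.3 and 45.1 ± 2.90 TPM on the same days. At day 3 and day 7 some libraries held both transcripts, such as day 3 library 2 with Xist at 8.17 and Ddx3y at 14.04 TPM and day 7 library 1 with Xist at 112 and Ddx3y at 6.79 TPM.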
